A study of Mus musculus and Homo sapiens with 73 samples.

How the data were processed

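RNA was measured in 15 libraries of mouse embryonic fibroblasts (MEFs), and chromatin regions came from CUT&Tag libraries of mouse and human spinal cord. CUT&Tag cuts and tags DNA beside the protein or histone mark that an antibody binds. The MEFs carried an alanine substitution at the caspase cleavage site of RIPK1 on both alleles and lacked Ripk3, per the labels' protocols, and were treated with vehicle, TNF, or TNF with Nec-1s, an inhibitor of the RIPK1 kinase. RNA was extracted with a column kit that includes a DNase step, per the labels' protocols. Bowtie2 2.3.4.3, deepTools 3.0.2, Salmon and DESeq2, and the builds mm9 and hg19, are named in the submitters' processing notes without their order, so the tool that made each table and its annotation are not given in the sources used here.

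The deposited RNA values were gene-level normalized counts, a signal, in 1 table with the 2 h libraries and 1 with the 3 h libraries, each with 27716 gene symbols and the same 3 vehicle libraries, whose columns were named 3 h in both tables per the file headers. Each column consisted of whole multiples of 1 step, as gene counts divided by 1 size factor per library give. Dividing by that step returned whole reads for 100% of the values above 0, within 0.1 of a read. The tables were scaled separately by the authors. Of the vehicle genes above 0, between 35.3% and 36.4% had the same recovered reads in both tables, and 1.11% to 1.34% of the genes with 100 or more reads differed by over 10%. Levels were therefore tested within a table only. All 27716 symbols matched the gene name table, and 23763 matched RefSeq (GRCm38). Rows covered 79.3% of RefSeq protein-coding symbols, from 53.7% on chromosome 13 to 96.3% on chromosome 11, and 327 of 391 listed genes. Nfkbia, Icam1, Sod2, Junb and Cyp1a1 were among the listed genes not analysed here.

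Genes with a mean normalized count of at least 10 in a table were tested on the log2 scale after adding a pseudocount of 1, which understates the change of low genes, with limma (trend, Benjamini-Hochberg adjusted p under 0.05). The 3 groups of a table shared 1 estimate of the spread. 22 gene lists fixed beforehand were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists with at least 2 tested genes. List p-values in the text are at the preset correlation unless stated, and depend on the correlation assumed between genes. List calls printed without a 2nd value held with an estimated correlation, at larger adjusted p of 2.1e-04 to 0.0412. Counts for a list are given over all genes tested and adjusted over the list alone. The named genes were those with adjusted p under 0.05, a mean of at least 50 in 1 of the groups and groups that did not overlap, up to 10 with the largest rise and 10 with the largest fall in each comparison. Up to 4 called members of each list, Ripk1 and Ripk3 stood beside them. Unnamed gene models were counted and not named. The text prints mainly those named genes whose call held with each library left out, a choice made after the result was seen. They were 32 of 46 for TNF at 2 h, 12 of 25 for TNF with Nec-1s against TNF at 2 h and 40 of 53 against vehicle, and 40 of 55, 21 of 43 and 45 of 59 at 3 h. Gene lists, comparisons, the main tests and the naming rule were set before the data were examined, and tests added later are named as such. Labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries.

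Count tests were added once reads had been recovered. edgeR's quasi-likelihood test called 348 rises and 180 falls for TNF at 2 h, 7 and 42 for TNF with Nec-1s against TNF at 2 h, 545 and 335 for TNF at 3 h, and 42 and 177 for TNF with Nec-1s against TNF at 3 h. DESeq2 called 466 and 259, 60 and 178, 658 and 369, and 102 and 347. Libraries held 8810819 to 11463872 recovered reads, so a floor of 3 reads stood at 0.262 to 0.34 CPM, counts scaled to 1e+06 reads. Replicate pairs differed by more than sampling noise, with chi-square values of 4.84 to 10.8 per degree of freedom, so none was counted as 1 sample.

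The limma step was tested on simulated counts with 200 changed genes. These were drawn from genes with a mean of at least 50 recovered reads, so recovery among lower genes was not measured. For TNF with Nec-1s against TNF at 2 h (10051 genes) it recovered 24% of genes changed 1.25-fold, 52% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, with 5.15% false calls. For the 3 h comparison (10035 genes) it recovered 24%, 74%, 88% and 98%, with 6.58% false calls. For effects at 2 h and 3 h against the shared vehicle libraries, 20 simulations of unchanged groups gave the agreement that shared controls bring.

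Human region lists gave a start and an end per region, without a score, and were deposited on hg19 per the submitters' processing notes. Their file names give a false discovery rate of 0.05 for the H3K27ac, H3K4me1 and p-S166-RIPK1 lists. These names also read no input and relaxed. The caller, and whether libraries were pooled, are not given in the sources used here. Repeated lines and chromosome Y were left out. Overlap of at least 1 bp was counted with bedtools and compared with 1000 circular shifts within chromosomes, whose smallest possible p is 0.001, and with 1000 shifts of at most 1 Mb. On simulated regions with 0%, 10% and 30% of regions placed, the step returned -1.06%, 7.85% and 26.8%. The mouse list (mm9 per the submitters' processing notes) held a deposited score per region, the signal summed over it, and the highest signal within it, both of unstated scaling. Values in the region lists are the authors' and serve here to describe each list. No annotation of mm9 or hg19 was used, so regions are given by position. MEF CUT&Tag libraries and MEF libraries without an antibody were not analysed here.

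Alternatives tried were a pseudocount of 8, no filter on low values, quantile normalization, robust variance shrinkage, only the 2 groups compared, a minimum fold change of 2, the replicate number as a block, each library left out in turn, the 2 count tests, an overlap of at least 0.5 of the region, the wider regions only, and local shifts. Floors cover counting error only. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, bedtools 2.31.1, numpy 2.4.6 and pandas 2.3.3.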

Results

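Gene expression was measured in MEFs that lacked Ripk3 and carried an alanine substitution at the caspase cleavage site of RIPK1, treated with vehicle, TNF, or TNF with Nec-1s. The series had 73 libraries, 50 from mouse and 23 from human. RNA came from 15 libraries in 5 groups of 3, with 8810819 to 11463872 recovered reads each. Mitochondrial genes held 3.00% to 4.39% of the reads. Levels below are normalized counts, given as mean ± SD with n = 3, and changes are log2 differences ± SE from limma with Benjamini-Hochberg adjustment.

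Ripk3, which encodes the kinase that drives necroptosis, was at 0 in all 15 libraries, where a true level below 0.262 to 0.34 CPM (counts scaled to 1e+06 reads) would go unseen. Ripk1, the kinase that Nec-1s inhibits, was expressed at 492 ± 70.5 with vehicle, 527 ± 42.4 with TNF and 542 ± 106 with TNF and Nec-1s at 2 h. At 3 h Ripk1 was at 447 ± 23.7 with TNF and 544 ± 13.0 with TNF and Nec-1s. None of the 6 comparisons called Ripk1, and its largest difference was 0.28 ± 0.10 (adjusted p = 0.181) for TNF with Nec-1s against TNF alone at 3 h.

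TNF raised inflammatory genes at 2 h. The vehicle columns were named 3 h. Differences from vehicle at 2 h, with or without Nec-1s, may therefore also hold a difference in time. Csf2, a myeloid growth factor, rose most among the named genes whose call held with any library left out (4.30 ± 0.20, 288 ± 49.6 against 13.8 ± 3.52, adjusted p = 5.2e-07). The chemokine genes Ccl20 (3.78 ± 0.14, 505 ± 27.7 against 36.2 ± 7.68), Cxcl2 (3.55 ± 0.13, 643 ± 19.97 against 54.7 ± 9.16) and Ccl2 (2.19 ± 0.04, 15042 ± 201 against 3301 ± 125) rose with it. Their products recruit leukocytes. Lif (2.95 ± 0.10, 8408 ± 753 against 1087 ± 141) and Il6 (2.82 ± 0.15, 606 ± 54.8 against 85.9 ± 17.3), which encode cytokines of the gp130 family, rose. So did Tnfaip3 (2.24 ± 0.06, 5181 ± 185 against 1095 ± 24.1), which encodes the NF-kB inhibitor A20. Smaller rises were those of Vcam1, a leukocyte adhesion gene (1.12 ± 0.05, 5269.6 ± 130.0 against 2419 ± 91.1), and Jun, a subunit of AP-1 (0.82 ± 0.06, 2380.0 ± 185 against 1350.0 ± 41.1). Bid, a BH3-only death gene, rose too (0.85 ± 0.08, 601 ± 36.5 against 332 ± 3.45). Falls were shallower, with the transcription factor gene Atoh8 (-1.08 ± 0.11, 311 ± 17.8 against 659 ± 69.8) and the BMP effector Smad9 (-1.02 ± 0.11, 311 ± 48.3 against 625 ± 19.3) among them. Also lower was the interferon regulator Irf7 (-0.63 ± 0.11, 254 ± 21.3 against 394 ± 41.8). Mlh3, a mismatch repair gene, was at 0 with vehicle and 71.1 ± 0.786 with TNF (adjusted p = 0.0262), a call lost with any of the 6 libraries left out (adjusted p from 0.0728 to 0.0832). Mlh3 was among 134 genes at 0 in some libraries and at 50 or more in others, whose cause was not found, and the TNF libraries at 3 h held 74.7, 0 and 78.7. Among TNF and NF-kB response genes 19 of 21 rose (21 adjusted over the list alone; median 1.06, camera adjusted p = 7.2e-33). Rises were called for 10 of 12 chemokines (10, and 1 fall, adjusted over the list alone; median 1.70, adjusted p = 1.2e-19). They were called too for 8 of 13 inflammatory cytokines (9 adjusted over the list alone; adjusted p = 3.4e-11) and 12 of 21 immediate early genes (12, and 1 fall, adjusted over the list alone; adjusted p = 1.4e-08). Interferon-stimulated genes shifted down (median -0.25, 3 of 35 called lower and 1 higher and 7 lower adjusted over the list alone; adjusted p = 4.1e-04), a call lost at adjusted p = 0.389 with an estimated correlation. Calls of the aryl hydrocarbon receptor (AhR) targets (1 of 5 lower, 1 adjusted over the list alone; adjusted p = 0.0412) and matrix genes (1 of 16 higher and 2 lower, 1 and 5 adjusted over the list alone; adjusted p = 0.0128) were lost too, at adjusted p = 0.225 with an estimated correlation and at adjusted p = 0.315 with an estimated correlation. Over the 10043 genes tested, 348 rose and 196 fell, 68 and 13 of them at least 2-fold. Without adjustment 1854 genes passed 0.05, and 25.0% of genes had groups that did not overlap, against 10% by chance. Leaving out 1 library lowered the falling genes to 111, 128 and 121 (TNF 2 h 1, 2 and 3) and to 116, 89 and 95 (vehicle 1, 2 and 3).

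At 3 h the same inflammatory genes stood out. Csf2 (4.04 ± 0.20, 235 ± 37.2 against 13.5 ± 3.43), Cxcl2 (3.59 ± 0.14, 651 ± 82.7 against 53.4 ± 8.93) and Ccl20 (3.27 ± 0.16, 346 ± 41.9 against 35.4 ± 7.48) rose over vehicle. Lif (2.89 ± 0.11, 7861 ± 893 against 1058 ± 137) and Tnfaip3 (2.02 ± 0.06, 4389 ± 233 against 1083 ± 24.0) followed. Mmp9, a gelatinase gene (2.50 ± 0.23, 111 ± 11.4 against 19.4 ± 6.30), and Nfkb1, which encodes the p50 subunit of NF-kB (0.89 ± 0.04), were also higher. Hspa5, the main chaperone of the endoplasmic reticulum (0.46 ± 0.03, 20568 ± 683 against 14989.8 ± 525), and Slc7a11, a cystine transporter gene (1.02 ± 0.07, 753 ± 24.5 against 369.6 ± 7.03), rose as well. Rasl11a, a Ras-like GTPase gene, fell (-1.46 ± 0.09, 348 ± 37.1 against 957 ± 91.0), with Arsi, a sulfatase gene (-1.14 ± 0.22). Rises took in 20 of 23 TNF and NF-kB response genes (21 adjusted over the list alone; median 0.96, adjusted p = 4.5e-27). They took in 11 of 12 chemokines, with 1 lower (11 and 1 adjusted over the list alone; adjusted p = 4.8e-18), and 7 of 13 cytokines (10 adjusted over the list alone; adjusted p = 8.9e-10). Among immediate early genes 12 of 21 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 8.9e-10), a list call lost at adjusted p = 0.134 with an estimated correlation. Calls of the stress response list (2 of 14 higher, 2 adjusted over the list alone; adjusted p = 0.0475) and matrix genes (2 of 16 higher and 4 lower, 2 and 7 adjusted over the list alone; adjusted p = 0.0195) were lost at adjusted p = 0.284 with an estimated correlation and at adjusted p = 0.618 with an estimated correlation. Of 10031 genes tested, 582 rose and 316 fell, or 461 and 384 after quantile normalization, which moved the share of rises from 64.8% to 54.6%. At least 2-fold were 81 and 21. Without adjustment 2204 genes passed 0.05, and 26.6% of genes had non-overlapping groups (10% by chance). The falling genes numbered 195 without TNF 3 h 1, 193 without vehicle 2 and 197 without vehicle 3.

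Effects of TNF at 2 h and 3 h shared 309 rising genes (20.3 by chance) and 137 falling genes (6.22 by chance) among 9960 genes tested in both tables, with none in opposite directions. The Spearman correlation was 0.690, against 0.457 in simulations where only the vehicle libraries were shared. Covariance of the effects was 0.103 against 0.0392 simulated. The 20 simulations shared 0 calls, but unchanged groups are seldom called, so this sets no level for the shared genes. Part of the excess of shared genes over independent lists may come from the shared vehicle libraries, which at 3 do not split into sets of at least 2.

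Nec-1s lowered TNF-raised genes at 2 h. No RNA library had Nec-1s without TNF, so whether such falls need TNF cannot be told here or at 3 h. Tnfaip3 fell against TNF alone (-1.01 ± 0.06, 2577 ± 186 against 5181 ± 185, adjusted p = 3.3e-05), as did the cytokine gene Lif (-0.88 ± 0.10, 4554 ± 361 against 8408 ± 753). The chemokine genes Cxcl2 (-1.09 ± 0.13, 303 ± 30.8 against 643 ± 19.97) and Cxcl1 (-0.59 ± 0.05, 4478 ± 165 against 6768 ± 394) fell as well. Ier3, an early response gene that limits apoptosis, fell (-0.75 ± 0.06, 2957 ± 201 against 4958 ± 247). A further group of falls were AhR targets. They were Cyp1b1, a cytochrome P450 gene (-1.28 ± 0.09, 566 ± 59.1 against 1377 ± 131), Ahrr, the AhR repressor (-1.14 ± 0.12, 61.4 ± 5.69 against 137 ± 9.07), and Tiparp, an ADP-ribosyltransferase gene (-0.92 ± 0.05, 918 ± 10.5 against 1741 ± 51.3). Mknk2, a kinase gene of the MAPK pathway (0.64 ± 0.07, 1274 ± 46.9 against 821 ± 67.3), and the linker histone gene Hist1h1c (0.61 ± 0.07, 1000.2 ± 57.1 against 657 ± 13.9) rose. Csf2 fell (-1.47 ± 0.20, 102 ± 9.26 against 288 ± 49.6, adjusted p = 0.0102), a call lost without TNF with Nec-1s 2 h 1 (adjusted p = 0.0504), TNF 2 h 1 (0.0631) or TNF 2 h 2 (0.0538). Larger falls, those of Lpin1 (-5.11 ± 0.89), a phosphatidate phosphatase gene, and Rrp8 (-1.95 ± 0.35), a ribosome processing gene, each lost their call with 5 of the 6 libraries left out in turn (adjusted p up to 0.146 and 0.169). Both were among the 134 genes that switched between 0 and 50 or more, and Lpin1 with TNF and Nec-1s was at 13.6, 0 and 0 at 2 h but at 61.2 to 93.9 at 3 h. Falls were called for 5 of 21 TNF and NF-kB response genes (11 adjusted over the list alone; median -0.20, adjusted p = 2.1e-09) and 4 of 12 chemokines (10 adjusted over the list alone; median -0.39, adjusted p = 3.7e-09). Further falls were those of 2 of 13 cytokines (4 adjusted over the list alone; median -0.45, adjusted p = 2.4e-07) and 2 of 21 immediate early genes (8 adjusted over the list alone; adjusted p = 4.3e-07). AhR targets fell in 3 of 5 (3 adjusted over the list alone; median -0.92, adjusted p = 6.3e-09). Cholesterol synthesis genes shifted up as a list of 17 (median 0.20, adjusted p = 1.7e-07, or 0.0353 with an estimated correlation), with 0 called over all genes and 8 adjusted over the list alone. The myofibroblast list shifted down (1 of 9 lower, 4 adjusted over the list alone; adjusted p = 5.3e-04), a call lost at adjusted p = 0.155 with an estimated correlation. In all, 7 genes rose and 47 fell, 0 and 8 at least 2-fold. Without adjustment 1301 passed 0.05, and 18.0% had non-overlapping groups (10% by chance). DESeq2 called 60 and 178. With only the 2 groups compared the falls numbered 27. Rises and falls were 4 and 25 without TNF with Nec-1s 2 h 1, 3 and 21 without TNF 2 h 1, and 3 and 18 without TNF 2 h 2, and the falls 29 without TNF 2 h 3.

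Falls with Nec-1s were more numerous at 3 h. Csf2 (-1.69 ± 0.20, 72.1 ± 7.63 against 235 ± 37.2), Cxcl2 (-1.41 ± 0.14, 244 ± 23.0 against 651 ± 82.7), Tnfaip3 (-1.22 ± 0.06, 1879 ± 130.2 against 4389 ± 233) and Lif (-0.99 ± 0.11, 3967 ± 414 against 7861 ± 893) fell against TNF alone. Ccl2 fell less (-0.40 ± 0.04, 11450.5 ± 161 against 15117 ± 804). The AhR targets Ahrr (-1.42 ± 0.13, 47.2 ± 4.01 against 128 ± 14.6), Cyp1b1 (-1.41 ± 0.07, 546 ± 51.2 against 1449 ± 110.5) and Tiparp (-1.07 ± 0.06, 911 ± 32.9 against 1913 ± 101) fell again. Rgs16, a regulator of G-protein signalling (-0.88 ± 0.08, 1244 ± 55.9 against 2295 ± 248), and Btg2, an antiproliferative gene (-0.74 ± 0.08, 237 ± 2.30 against 399 ± 40.9), were lower. Ccn2, a matricellular target of TGF-beta, fell (-0.48 ± 0.06, 6198 ± 169 against 8681 ± 730.2). Hist1h1c (0.72 ± 0.06, 931 ± 15.8 against 564 ± 9.03), Pcyox1, a prenylcysteine oxidase gene (0.66 ± 0.07, 820.0 ± 70.0 against 519 ± 16.8), and Crot, a peroxisomal acyltransferase gene (0.61 ± 0.09, 261 ± 10.5 against 171 ± 2.16), rose. Lower were 8 of 23 TNF and NF-kB response genes (12 adjusted over the list alone; median -0.25, adjusted p = 1.7e-10) and 6 of 12 chemokines (9 adjusted over the list alone; median -0.42, adjusted p = 3.7e-10). Lower too were 4 of 13 cytokines (7 adjusted over the list alone; adjusted p = 4.5e-06) and 3 of 5 AhR targets (3 adjusted over the list alone; median -1.07, adjusted p = 3.5e-06). Cholesterol synthesis genes rose in 4 of 17 (10 adjusted over the list alone; median 0.20, adjusted p = 8.2e-08). With an estimated correlation the camera adjusted p of the cholesterol list was 0.0412. Called members included Cyp51 (0.22 ± 0.04), Sqle (0.19 ± 0.04) and Nsdhl (0.32 ± 0.07), enzymes of sterol synthesis. Each of these lost its call with any of the 6 libraries left out (adjusted p up to 0.104, 0.140 and 0.130). Immediate early genes fell in 6 of 21 (12 adjusted over the list alone; adjusted p = 9.4e-08) and myofibroblast genes in 5 of 9 (5 adjusted over the list alone; adjusted p = 2.8e-04), calls lost at adjusted p = 0.122 with an estimated correlation and at adjusted p = 0.0788 with an estimated correlation. Matrix genes (2 of 16 lower, 2 adjusted over the list alone; adjusted p = 0.0173) lost theirs at adjusted p = 0.519 with an estimated correlation. Quantile normalization moved the matrix median from -0.0737 to 0.000906 and the myofibroblast median from -0.193 to -0.0506. In total 43 genes rose and 208 fell, 2 and 9 at least 2-fold. Without adjustment 1647 passed 0.05, and 21.5% had non-overlapping groups (10% by chance). Quantile normalization left 93 falls, only the 2 groups compared gave 16 and 106, and DESeq2 gave 102 and 347. Leaving out 1 library gave 16 and 81, 15 and 78, or 11 and 67 (TNF with Nec-1s 3 h 1, 2 and 3) and 11 and 64, 14 and 72, or 20 and 133 (TNF 3 h 1, 2 and 3).

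**Figure D1:**
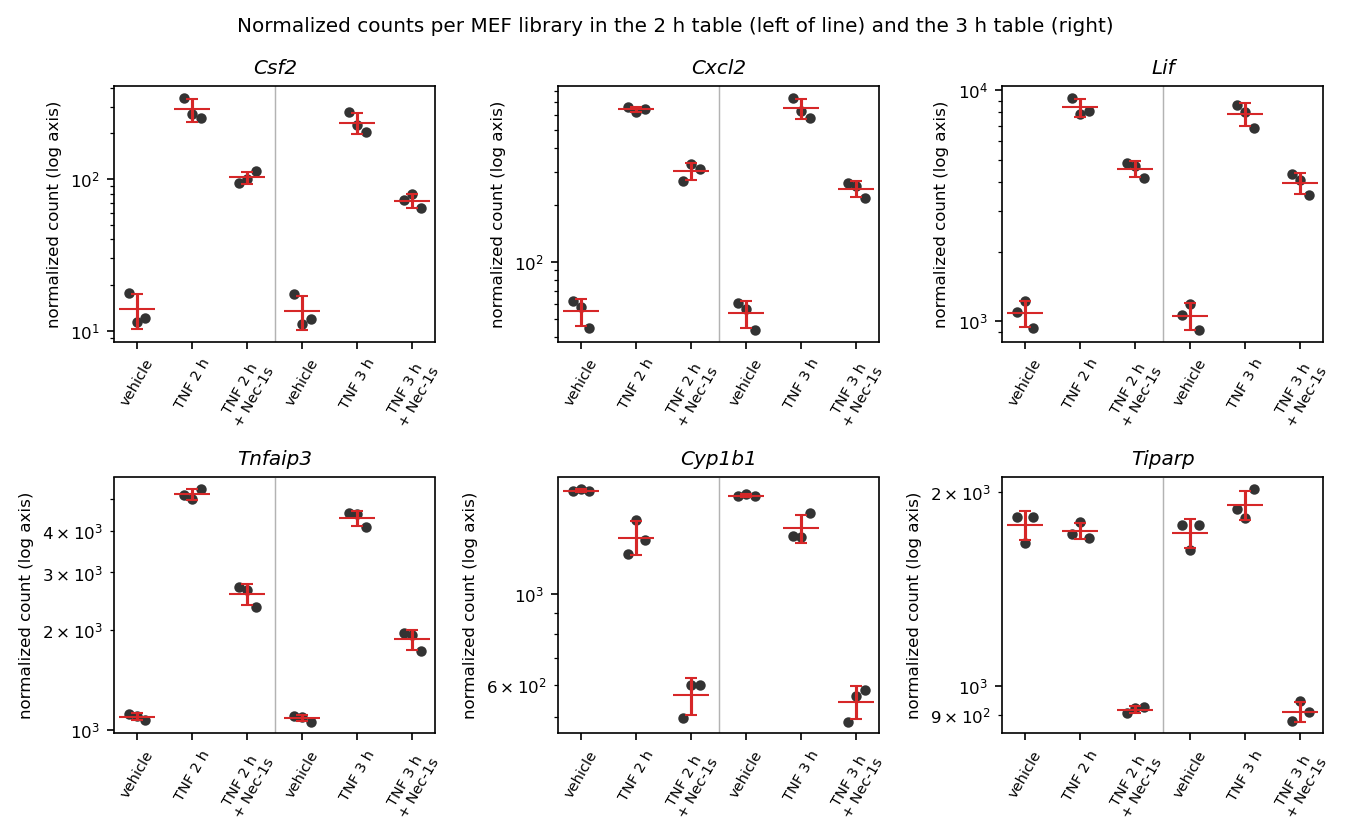
Normalized counts of 6 genes per library with mean ± SD (n = 3). Csf2 went from 13.5 with vehicle to 235 with TNF and 72.1 with TNF and Nec-1s at 3 h, and Cyp1b1 from 1743 to 546 with TNF and Nec-1s.

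Genes that TNF raised in 1 table were followed in the other, so that the TNF libraries of a comparison did not also choose its genes. Of the 81 genes raised at least 2-fold at 3 h, 79 were tested at 2 h, and their median Nec-1s effect there was -0.29 (66 below 0, 13 called; camera p = 5.5e-21, or 0.000492 with an estimated correlation). The median fold over vehicle was 2.45 with TNF and 2.05 with TNF and Nec-1s. These folds, and those of the next set, use the vehicle libraries that also chose the genes, which can inflate them. For the 68 genes raised at 2 h the median Nec-1s effect at 3 h was -0.48 (63 below 0, 24 called; camera p = 3.8e-29, or 0.00122 with an estimated correlation), and the folds were 2.98 and 2.14. Among genes lowered by Nec-1s, 28 of 47 at 2 h were TNF-raised at 3 h (2.74 by chance, Fisher p = 3.5e-23), and 83 of 208 at 3 h were TNF-raised at 2 h (7.27 by chance, p = 4.6e-68). Genes raised by Nec-1s and lowered by TNF were 1 of 7 (0.222 by chance, Fisher p = 0.202) and 7 of 43 (0.846 by chance, p = 1.8e-05). Fisher's test treats genes as independent, which co-regulated genes are not, so these p-values do not measure the spread between libraries. Nec-1s lowered 37 genes at both times (0.982 by chance) and raised 3 (0.0302 by chance), and the Spearman correlation of its effects was 0.348 over 9960 genes.

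With TNF and Nec-1s, inflammatory genes stayed above vehicle while AhR targets fell below it. Ccl20 (3.28 ± 0.14, 357 ± 17.3 against 36.2 ± 7.68), Csf2 (2.83 ± 0.20) and Lif (2.07 ± 0.10) were raised at 2 h, and at 3 h the rises were 2.73 ± 0.16, 2.36 ± 0.20 and 1.91 ± 0.11. Slc7a2, a cationic amino acid transporter gene, rose at 2 h (1.78 ± 0.07, 4534 ± 400.4 against 1318 ± 99.6) and 3 h (1.91 ± 0.05). Gadd45a, a stress-induced growth arrest gene, rose at 3 h (1.09 ± 0.11, 203 ± 1.80 against 95.3 ± 5.23). Cyp1b1 (-1.67 ± 0.09, 566 ± 59.1 against 1792 ± 13.2), Ahrr (-1.47 ± 0.12, 61.4 ± 5.69 against 171 ± 4.08) and Tiparp (-0.95 ± 0.05, 918 ± 10.5 against 1779 ± 94.4) fell below vehicle at 2 h. At 3 h the differences of Cyp1b1, Ahrr and Tiparp were -1.68 ± 0.07, -1.79 ± 0.13 and -0.92 ± 0.06, and Dio3, a thyroid hormone deiodinase gene, fell most among the named genes (-2.61 ± 0.35, 7.11 ± 0.691 against 50.1 ± 15.2). At 2 h rises were called for 18 of 21 TNF and NF-kB response genes (19, and 1 fall, adjusted over the list alone; adjusted p = 7.1e-25) and 8 of 12 chemokines (11, and 1 fall, adjusted over the list alone; adjusted p = 4.2e-17). Rises were called for 6 of 13 cytokines (8 adjusted over the list alone; adjusted p = 4.7e-07) and falls for 3 of 5 AhR targets (4 adjusted over the list alone; adjusted p = 7.5e-09). At 3 h 17 of 23 TNF and NF-kB response genes rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 3.7e-20). Of the chemokines 10 of 12 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 2.1e-15). Cytokines rose in 6 of 13 (6 adjusted over the list alone; adjusted p = 2.1e-07) and AhR targets fell in 3 of 5 (3 adjusted over the list alone; adjusted p = 2.6e-06). Cholesterol synthesis genes rose in 6 of 17 at 2 h (10 adjusted over the list alone; adjusted p = 5.1e-05) and 10 of 17 at 3 h (12 adjusted over the list alone; adjusted p = 1.6e-06), calls lost at adjusted p = 0.0933 with an estimated correlation and at adjusted p = 0.0655 with an estimated correlation. Matrix genes shifted down, with 4 of 16 lower and 1 higher at 2 h (1 higher and 7 lower adjusted over the list alone; adjusted p = 5.1e-05) and 7 of 16 lower and 1 higher at 3 h (1 higher and 12 lower adjusted over the list alone; adjusted p = 5.6e-06), also lost at adjusted p = 0.0933 with an estimated correlation and at adjusted p = 0.157 with an estimated correlation. Interferon-stimulated genes fell in 4 of 35 at 2 h (6 adjusted over the list alone; adjusted p = 5.1e-05), lost at adjusted p = 0.234 with an estimated correlation. At 3 h the interferon-stimulated list was not called, either with TNF and Nec-1s (2 of 36 higher and 2 lower, the same adjusted over the list alone; median -0.03, adjusted p = 0.971) or with TNF (2 of 36 higher, 2 adjusted over the list alone; median -0.12, adjusted p = 0.586). In all 283 genes rose and 204 fell at 2 h, and 388 and 355 at 3 h, with 45 and 13, and 49 and 19, at least 2-fold. Quantile normalization turned the majority at 3 h, to 363 rises and 397 falls (52.2% to 47.8% rises). Without adjustment 1781 and 1964 genes passed 0.05, and 23.6% and 26.2% had non-overlapping groups (10% by chance). At 2 h rises fell to 1.7e+02 (rounded) without TNF with Nec-1s 2 h 2, 182 without vehicle 2 and 183 without vehicle 3. Falls dropped to 131 and 126 without TNF with Nec-1s 2 h 1 and 2, and 116, 101 and 111 without vehicle 1, 2 and 3. At 3 h rises and falls were 246 and 228 without TNF with Nec-1s 3 h 1, 254 and 229 without TNF with Nec-1s 3 h 2. Falls numbered 202 without vehicle 2 and 211 without vehicle 3.

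**Figure D2:**
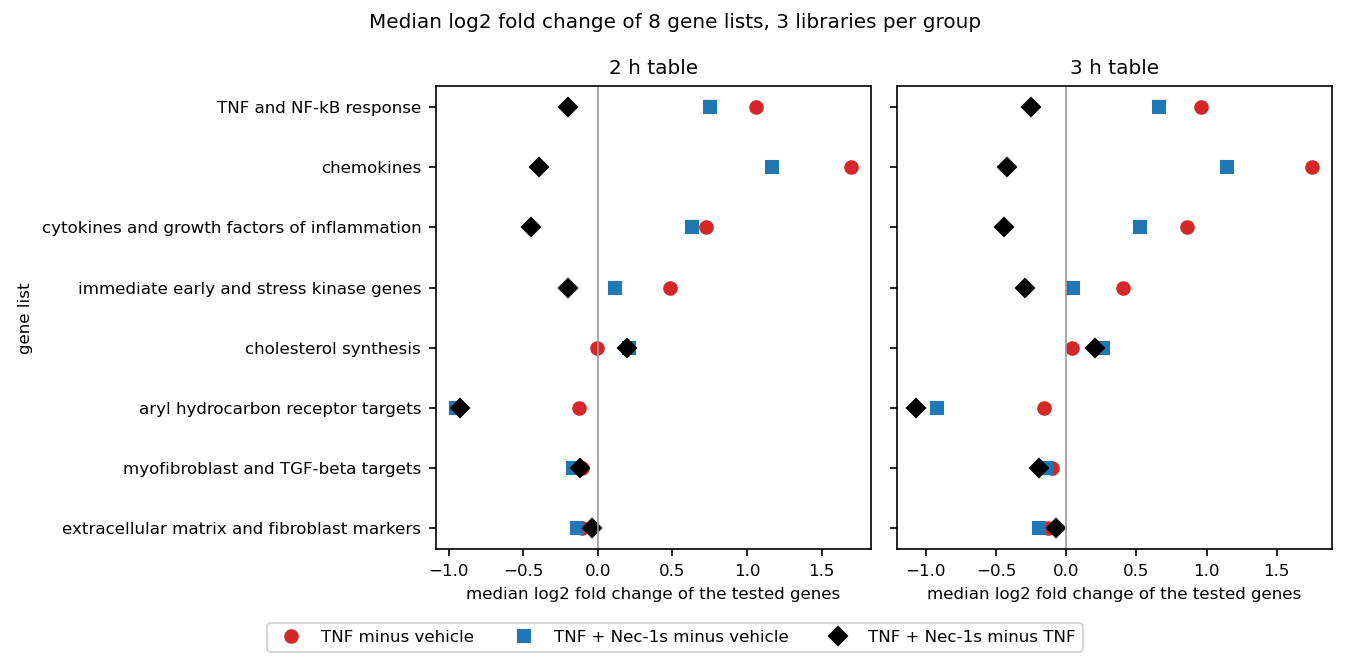
Median log2 difference of 8 gene lists in the 3 comparisons of each table. The AhR target medians against TNF alone were -0.92 at 2 h and -1.07 at 3 h, and the chemokine medians -0.39 and -0.42.

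In human spinal cord, p-S166-RIPK1 regions, from an antibody to autophosphorylated RIPK1, met regions of the histone marks H3K27ac and H3K4me1 more often than shifted regions did. The lists without chromosome Y held 70467 p-S166-RIPK1, 218072 H3K27ac and 113956 H3K4me1 regions, all with a median width of 300 bp. The p-S166-RIPK1, H3K27ac and H3K4me1 lists stand in descriptions of 4, 4 and 3 ALS libraries and of 4, 2 and 2 control libraries. These lists were named for ALS and the lists of active promoters and enhancers for ALS against control, and which tissue has the higher signal is not stated. By their names, the enhancer list took in a numbered item that the promoter, H3K27ac and H3K4me1 lists left out. The shares of these lists may therefore rest on different libraries. Of the p-S166-RIPK1 regions 6000 (8.51%) overlapped H3K27ac regions, against 4.76 ± 0.107% after circular shifts (1.79 times) and 5.66% after shifts of at most 1 Mb (1.504 times). H3K4me1 was met by 5634 regions (7.995%), against 2.59 ± 0.0817% (3.09 times) and 3.49% (2.29 times). Both marks were met by 522 regions (0.741%), H3K27ac alone by 5478 (7.77%), H3K4me1 alone by 5112 (7.25%), and 59355 (84.2%) met neither. The list of active enhancers had 4042 distinct regions, 251 of them (6.21%) over p-S166-RIPK1 regions against 1.82 ± 0.210% (3.41 times; 2.47 times with local shifts). All enhancer regions (100%) overlapped H3K4me1 regions, against 4.62% of promoter regions, so the enhancer share is not independent of the H3K4me1 overlap. The list of active promoters had 8589, with 253 (2.95%) against 1.65 ± 0.143% (1.79 times; 1.37 times with local shifts). H3K27ac regions met H3K4me1 regions in 4.27% against 2.59 ± 0.0538% (1.65 times), a smaller excess than p-S166-RIPK1 regions had over H3K4me1 regions. The H3K27ac, H3K4me1 and p-S166-RIPK1 lists are named as made without input. Whether signal common to the antibodies adds to the overlaps was not tested. Every p was 0.001, the smallest that 1000 shifts can give. All promoter regions (100%) and 3960 enhancer regions (98.0%) were identical to H3K27ac regions, and 193 promoter regions were identical to enhancer regions. Shares per autosome ran from 7.38% to 9.40% for H3K27ac and from 6.83% to 9.84% for H3K4me1. The widest p-S166-RIPK1 region was chr2:133025401-133033800 (8400 bp), and the fifth widest H3K4me1 region, chr2:133031901-133035150, overlapped it. The lists carry no score and no direction between ALS and control tissue, so no such comparison was made, and the promoter and enhancer shares were not tested against each other.

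**Figure D3:**
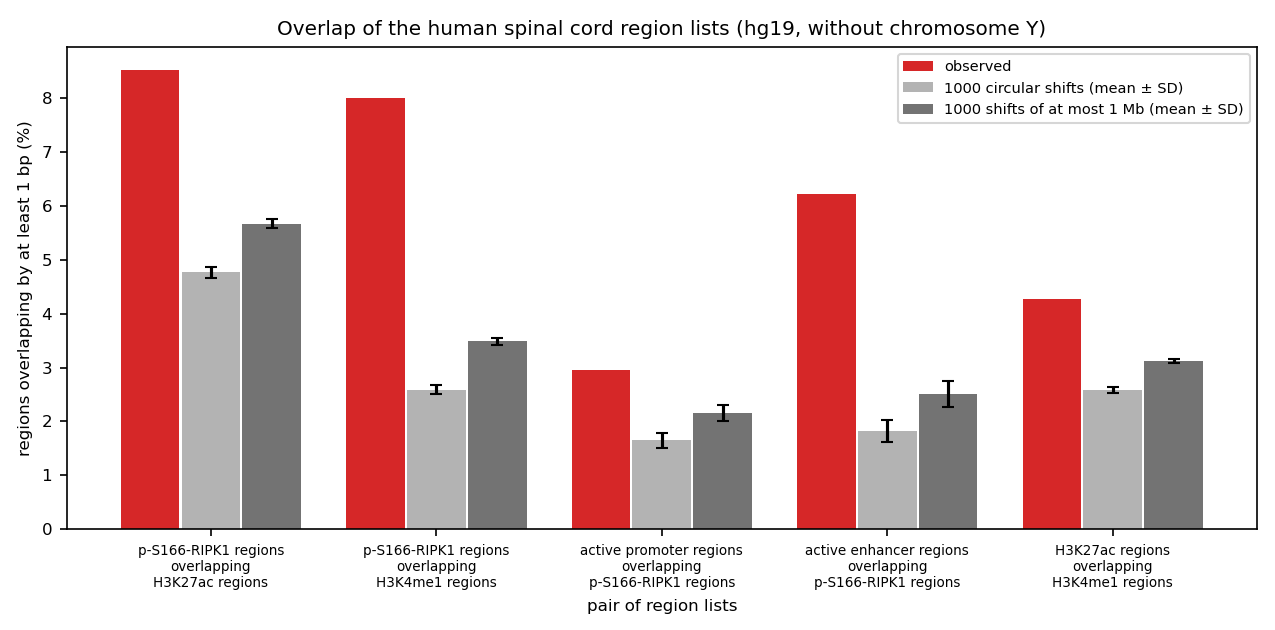
Percent of regions overlapping another list, beside circular shifts and shifts of at most 1 Mb. The p-S166-RIPK1 regions over H3K4me1 stood at 7.995% against 2.59% and 3.49%.

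In mouse spinal cord, the p-S166-RIPK1 list on H3K27ac regions held 77261 distinct regions in 85472 lines, covering 21.05 Mb with a median width of 200 bp. Its name gives DKO, KD and WT libraries and ends in a DKO library, and which library the signal is from is not stated. The median summed signal was 742 and the median highest signal 4.54. Regions with the highest summed signal were chr5:107635901-107637300 (7082), chr14:77930051-77930800 (6649), chr13:58929701-58930650 (6123), chr12:13366501-13367250 (5474) and chr13:49286201-49286950 (5474). Among regions with a summed signal above the median the median width was 300 bp, and a sum over a region grows with its width. The list has 1 signal per region and no value per genotype, so no genotypes were compared.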

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

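The tests of effects against time were added after the data had been seen, and the test of zeros within a group was chosen after the result was seen, whereas those of sampling and of overlapping gene models were set before it. Their verdicts below rest on other limits than those set beforehand. By the limits set beforehand, sampling would not have been ruled out and overlapping gene models would have been.

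The effect of TNF or of Nec-1s differed between 3 h and 2 h in very few genes, and each was at 0 in some whole groups. For Yeats2, a subunit of a histone acetyltransferase complex, the Nec-1s effect was lower at 3 h by -7.91 (adjusted p = 0.00680) and the TNF effect higher by 6.98 (adjusted p = 0.0125). Yeats2 was at 0 in all 3 TNF libraries at 2 h. For Rps13-ps1, a ribosomal protein pseudogene, the TNF effect differed by -6.07 (adjusted p = 0.0238), and for Specc1l, a cytoskeletal gene, by -7.16 (adjusted p = 0.0476), each at 0 in all 3 TNF libraries at 3 h. These were 1 of 10048 genes for Nec-1s and 3 of 9960 for TNF, while 395 and 541 genes passed 0.05 without adjustment.

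Such values belong to a wider pattern that takes in Mlh3, Lpin1 and Rrp8 too: 103 genes in each table were at 0 in some libraries and at 50 or more in others, 134 in either table and 72 in both. Sampling of few reads might give such zeros, but 2.42 were expected by Poisson sampling in the 2 h table and 223 were seen, so this was ruled out as the whole cause. Treatment might give them, but 79.6% of these genes held both kinds of value within 1 group. Another explanation is that reads of a locus were assigned to 1 of several overlapping gene models. Overlapping RefSeq genes had more reads where the gene was at 0 in 47.1% of 17 pairs (exact binomial p = 1), which covers 15 of the 134 genes and leaves this open.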

How the results depend on the processing

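Both count tests were chosen after the data had been seen, and the other settings before. Of 234 values of 28 results under other settings, 165 stayed the same, 64 were weaker, 4 stronger, 0 reversed and 1 moved, and of 2870 values of 287 named gene results 489 were weaker and 6 reversed. A count of genes or lists was labelled the same within a set factor, so that a drop from 348 to 250 rises was the same. Such counts cannot reverse, so their lack of reversals carries no information. With each library left out the uncalled Ripk1 difference ranged from -0.00631 (vehicle 1) to 0.202 for TNF at 2 h, from -0.125 (TNF with Nec-1s 2 h 2) to 0.145 for TNF with Nec-1s against TNF at 2 h, from -0.0172 (TNF with Nec-1s 2 h 2) to 0.253 against vehicle at 2 h, and from -0.192 to 0.0184 (vehicle 2) for TNF at 3 h. It was -0.0360 for TNF with Nec-1s against TNF without TNF 2 h 3. Quantile normalization turned Fn1 for Nec-1s at 3 h to 0.0299. It also lowered the genes falling in that comparison from 208 to 93. A minimum fold of 2 left 68 rising and 13 falling genes for TNF at 2 h, 0 and 8 for TNF with Nec-1s against TNF at 2 h, 45 and 13 for TNF with Nec-1s against vehicle at 2 h, and 81 and 21, 2 and 9, and 49 and 19 at 3 h. With an estimated correlation the lists called went from 7 to 4 for TNF at 2 h, 10 to 4 for TNF with Nec-1s against vehicle at 2 h, 6 to 3 for TNF at 3 h, 8 to 5 for TNF with Nec-1s against TNF at 3 h and 8 to 4 against vehicle at 3 h. Only the 2 groups compared gave 27 falling genes for Nec-1s at 2 h, and 16 rising and 106 falling at 3 h. DESeq2 called 60 and 178 for Nec-1s at 2 h and 102 and 347 at 3 h. With each library left out, rising and falling genes ranged over 250 to 283 and 89 to 128 for TNF at 2 h, 3 to 9 and 18 to 34 for TNF with Nec-1s against TNF at 2 h, 1.7e+02 (rounded) to 243 and 101 to 147 against vehicle at 2 h, 424 to 506 and 193 to 263 for TNF at 3 h, 11 to 20 and 64 to 133 for TNF with Nec-1s against TNF at 3 h, and 246 to 304 and 202 to 264 against vehicle at 3 h. The replicate number as a block lowered the falling genes for Nec-1s at 2 h from 47 to 29. Numbers gave no clear pairing of the libraries: in a check of pairing, 18 same-numbered pairs had r from -0.0911 to 0.127, with 2 over 0.1, and other pairs from -0.120 to 0.0770. At 2 h same-numbered pairs ran from -0.0884 to -0.0212. At 3 h they ran from -0.0911 to 0.127 and other pairs from -0.120 to 0.0593, so pairing at 3 h is not excluded. The block kept 169 of the 251 calls for Nec-1s at 3 h. Mouse regions with a summed signal above the median had a median width of 300 bp instead of 200 bp, which a sum over the region brings by itself. For the other changes the cause was not tested. The planned gene lists of the regions were not run, as no annotation of hg19 was used.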

Other observations

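Tests of the AhR targets and the splits of libraries were chosen after the result was seen, and those of the spread and of a larger effect at 3 h were set before it.

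Slc7a11, which encodes a cystine transporter and is a target of Nrf2, rose with TNF and Nec-1s over vehicle at 2 h (0.79 ± 0.08) and 3 h (1.09 ± 0.07), as did Srxn1, a peroxiredoxin reductase gene (0.49 ± 0.06 at 3 h), but the Nrf2 list was not called in either table. Flt1, an endothelial receptor gene, rose with TNF at 2 h (0.38 ± 0.07) and 3 h (0.60 ± 0.06), while Timp1, an inhibitor of metalloproteinases, rose (0.51 ± 0.04) and Col1a1, a collagen gene (-0.23 ± 0.04), and Pdgfrb, a growth factor receptor gene (-0.28 ± 0.04), fell at 3 h. With TNF at 2 h and 3 h, 0 and 1 of 22 cell cycle genes were called higher (0 and 1 adjusted over the list alone), and 0 and 1 of 9 heat shock genes (0 and 1 adjusted over the list alone). None of 9 p53 targets was called (1 lower at 2 h and 0 at 3 h adjusted over the list alone). Of 24 genes of TNF receptor signalling and cell death, 2 were higher at 2 h (2 higher and 1 lower adjusted over the list alone), and 2 higher and 1 lower at 3 h (3 and 1 adjusted over the list alone). Over all genes 544 of 10043 and 898 of 10031 were called, and none of these lists was. With TNF and Nec-1s over vehicle, immediate early genes (7 of 21 higher and 1 lower, 9 and 2 adjusted over the list alone), p53 targets (0 called, 0 adjusted over the list alone) and myofibroblast genes (2 of 9 lower, 4 lower and 1 higher adjusted over the list alone) were called as lists at 2 h (adjusted p = 0.00143, 0.0156 and 0.0132), and none with an estimated correlation (adjusted p = 0.115, 0.0933 and 0.259). At 3 h the stress response and myofibroblast lists were called (adjusted p = 0.0268 and 0.00536) and lost at adjusted p = 0.157 for both with an estimated correlation.

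The AhR targets Cyp1b1, Ahrr and Tiparp fell below vehicle with TNF and Nec-1s. Library scaling could not explain this, as the median at 3 h was -1.71 after quantile normalization. A return of a TNF rise to the vehicle level could not either at 2 h, as TNF alone gave no rise to return from (median -0.32, largest SE 0.12). At 3 h that median was -0.27, with Tiparp at 0.15 and not called over all genes. Adjusted over the list alone, Tiparp was called higher at 3 h and 2 of the 5 listed genes lower. An effect of the compound that does not need TNF may be the cause and stays open, as 0 RNA libraries had Nec-1s without TNF.

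Nec-1s changed 251 genes at 3 h and 54 at 2 h. A larger spread at 2 h may account for part or all of this. With the 3 h standard errors multiplied by the ratio of the spreads, 1.07, the 3 h count fell to 148. That stayed above 54. The ratio also took in the vehicle libraries, which both tables share and which are not in this comparison. Pairs of libraries within the TNF and TNF with Nec-1s groups had chi-square values of 6.72 to 10.8 per degree of freedom at 2 h. At 3 h the values were 4.84 to 7.53. Whether the spread accounts for all of the difference therefore stays open. Tested gene by gene, the Nec-1s effect differed between the times in 1 of 10048 genes. A larger effect at 3 h on TNF-raised genes may contribute: over 58 genes raised at both times the median difference was -0.11, with 45 of 58 lower at 3 h (camera p = 2.2e-04, or 0.128 with an estimated correlation), which leaves this open.

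The 6 libraries of a comparison allow 10 splits into 3 against 3, too few for a share under 0.05, and in each comparison 1 split, the real one, called as many genes. Real splits called 544, 54 and 487 genes at 2 h (TNF against vehicle, TNF with Nec-1s against TNF, and against vehicle) and 898, 251 and 743 at 3 h, and the highest other splits called 1, 2 and 2, and 4, 2 and 1.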
